A study of Arabidopsis thaliana with 6 samples.

How the data were processed

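Whole seedlings of Arabidopsis thaliana Col-0 were grown for 7 days on 1/2 Murashige-Skoog medium with 1% sucrose and 10 µM dexamethasone, per the labels' protocols, after 3 days of cold in water. Light was given for 16 h per day at 120 µmol m-2 s-1 and 21 °C, and nights were at 19 °C. Poly(A) libraries were sequenced on an Illumina NovaSeq, per the labels' protocols. The values used were the read counts per locus that the authors deposited, 32834 loci in 6 libraries. Per the submitters' processing notes, reads were trimmed with fastp, aligned with STAR to TAIR10 and counted with HTSeq. Tool versions, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. The deposited counts were whole numbers without normalization.

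Libraries were grouped as WT, MIF_1 and MIF_3 from their titles and genotypes, with 2 libraries per group. There were no libraries of seedlings with the vector alone or without dexamethasone. Gene names came from the TAIR10.1 reference (RefSeq), used for names and for which loci overlap; 32548 of the 32834 loci had a record there. The 133 plastid-encoded and 152 mitochondrion-encoded loci had none and are given by locus ID. AT2G33430 was the nuclear locus without a record, and its name MORF2 was fixed before the data were examined. Of 153 named genes, 43 overlap another annotated locus.

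Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 20438. TMM factors and a quasi-likelihood model with a coefficient per group over all 6 libraries were used, with 3 residual degrees of freedom, a prior of 6.69 and a common dispersion of 0.0174. Contrasts were MIF_1 against WT, MIF_3 against WT, the mean of MIF_1 and MIF_3 against WT, and MIF_3 against MIF_1. Genes with a Benjamini-Hochberg adjusted p below 0.05 over all genes tested were called. SE is a standard error derived from the test, the absolute log2 fold change over the square root of its quasi-likelihood F statistic. It is approximate, above all where a group is near 0 counts. CPM was computed from TMM-scaled library sizes. Folds against a group with no counts used a floor of 3 counts over the group, and those with 1 to 3 WT counts are ratios of pooled counts with exact 95% intervals; both cover counting error only.

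Gene lists, 32 in all, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. They covered light harvesting and photosystems, electron transport and carbon fixation, tetrapyrrole synthesis, and plastid-to-nucleus signalling. Others held the MORF family, plastid editing factors outside it, plastid transcription, plastid ribosomal proteins, plastid chaperones and proteases, and cytosolic heat shock. Further lists were mitochondrial dysfunction, seed storage, abscisic acid, gibberellin, salicylic acid, jasmonate and ethylene, reactive oxygen, flavonoids, light signalling, the clock, senescence, and the SCF and proteasome core. The remaining lists were cell cycle, iron, glucosinolates, root markers, shoot meristem and stomatal markers, reference genes, plastid-encoded, mitochondrion-encoded, F-box and pentatricopeptide repeat genes. Of 587 members written by symbol, 26 whose symbol the reference did not give were left out, but were tested among all genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were alternatives. With an estimated correlation and 3 residual degrees of freedom, 0 lists passed in each contrast. This held even for plastid-to-nucleus signalling, whose estimated correlation in the mean contrast was -0.037, below the preset. A list that fails there is therefore not shown to fail because its genes are correlated.

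The named genes were MORF2 and GUN1; the 10 largest rises and 10 largest falls of the mean contrast among genes called in both sets with an average log2 CPM of at least 1; the 3 largest in each direction in MIF_1 and in MIF_3 against WT, and the 5 largest in MIF_3 against MIF_1; and up to 4 members per list with the smallest p in the mean contrast.

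Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no or a stricter low-count filter (1 CPM and a mean count of 50), organelle-encoded genes removed, a replicate block, the libraries compared alone, a threshold of 0.01, a log2 limit of 1, and leaving out each library in turn. Removing rRNA genes as well was added after the data were seen. Where a left-out library leaves a group with 1 library, that library is assumed to vary like the other groups.

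The tests were tested on simulated data, with counts drawn for 20438 genes of which 200 were changed, in 10 simulations. A list of 30 further genes was moved in the same draws, and calls of these were not counted as false. For the mean contrast 35.8%, 73.9% and 91.8% of genes changed 1.5-fold, 2-fold and 4-fold were called, and 9% of calls were false. For MIF_1 against WT these were 22.5%, 66.6% and 88.2%, with 11.9% false, and for MIF_3 against WT 20.1%, 65.7% and 88.3%, with 9.6% false. The share of false calls was thus above the nominal level in these simulations. In the data 13.3% to 18.7% of genes were called against WT, far more than were changed here. The share of false calls depends on this, so it need not be the same in the data. Camera called a list of 30 genes moved by -0.5 in 10 of 10 simulations and 0 of 190 unmoved lists. The simulated genes were drawn independently, whereas the light-harvesting list had an estimated correlation of 0.881 in the mean contrast. The simulations therefore do not show how often camera calls lists of correlated genes falsely. Overlap of the sets was compared with 20 simulations in which all 6 libraries, WT included, were redrawn from the mean level of each gene. Both simulated sets were set against the same simulated WT libraries. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.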

Results

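Poly(A) RNA was sequenced from 7-day-old whole Arabidopsis thaliana Col-0 seedlings in 6 libraries. The 3 groups were wild type (WT) and the transgenic sets labelled MIF_1 and MIF_3, with 2 libraries each. Both sets carried Myc-tagged MIF in pTA7002, a vector from which dexamethasone switches on a transgene, and seedlings of all 3 groups grew on 10 µM dexamethasone. Total counts were 21.4e6 and 18.3e6 in WT, 22.4e6 and 22.8e6 in MIF_1, and 24.2e6 and 24.7e6 in MIF_3. Neither the meaning of the set numbers nor whether replicates were separate cultures is given in the labels, so p-values measure the spread between these samples.

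WT replicate 2 held a larger share of organelle-encoded and rRNA counts than the 5 other libraries. Plastid-encoded loci took 0.132% of its counts (95% Wilson interval 0.131% to 0.134%), against 0.0273% in WT replicate 1 (0.0266% to 0.0280%) and from 0.0203% to 0.0249% in the transgenic libraries. Nuclear rRNA loci took 1.04% of its counts (1.03% to 1.04%), against 0.437% in WT replicate 1 (0.434% to 0.440%) and from 0.298% to 0.468% in the transgenic libraries. These intervals cover counting error only. Counts of the replicates of a group differed by more than counting error, with a chi-square per degree of freedom of 11.6 in WT, 9.33 in MIF_1 and 25.1 in MIF_3. The first principal component, with 53.6% of the variance, separated WT from the transgenic libraries, and the second, with 18.1%, separated MIF_1 from MIF_3.

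**Figure D1:**
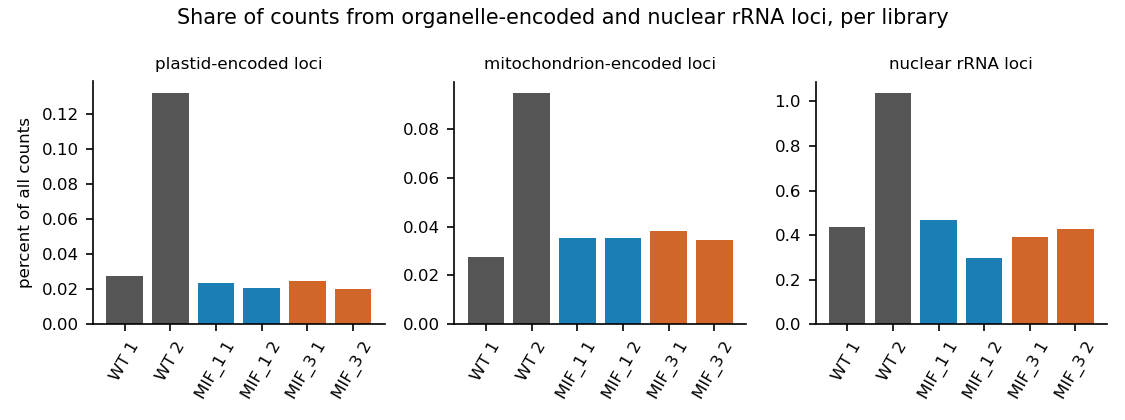
Share of all counts (percent) from plastid-encoded, mitochondrion-encoded and nuclear rRNA loci, with a bar per library. WT replicate 2 reached 0.132% for plastid-encoded loci, where the 5 other libraries lay between 0.0203% and 0.0273%.

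The series title names MORF2, a plastid RNA editing factor, and the design text asks which transcripts differ with MIF expression. The MORF2 transcript (AT2G33430) did not pass the test in either set. Its level was 101 ± 3.50 counts per 1e6 (CPM; SD, n = 2) in WT, 109 ± 3.06 in MIF_1 and 94.6 ± 3.11 in MIF_3. The log2 fold change was 0.11 ± 0.10 (SE, n = 2 against 2; edgeR adjusted p = 0.471) in MIF_1 and -0.09 ± 0.10 (adjusted p = 0.585) in MIF_3. GUN1 (AT2G31400), which acts in signalling from plastids to the nucleus, fell by 0.36 ± 0.08 log2 units (SE) in the mean of both sets (adjusted p = 0.0145). It had a log2 fold change of -0.43 ± 0.10 (adjusted p = 0.0154) in MIF_1 and did not pass in MIF_3 (-0.30 ± 0.10, adjusted p = 0.0769). Its level was 444 ± 2.48 CPM in WT, 330.0 ± 30.6 in MIF_1 and 361 ± 12.03 in MIF_3. The call in the mean ended without WT replicate 1 (adjusted p = 0.109), WT replicate 2 (0.0936) or MIF_1 replicate 2 (0.0582), and that in MIF_1 without the same libraries (0.0895, 0.0771 and 0.138). The sources used here do not name the locus of MIF, so its transcript could not be looked up. A search for it among F-box loci, given under the other observations, could not decide.

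The mean of MIF_1 and MIF_3 against WT tested the average effect of the sets, so it also called genes that changed in 1 of them. ZAT10 had a log2 fold change of -1.78 (adjusted p = 4.58e-05) in the mean but 0.05 (0.880) in MIF_1. Of 20438 genes tested, 1587 rose and 2235 fell, and 591 and 550 of these changed at least 2-fold. The median gene moved by 0.01 on the log2 scale. The calls numbered 2164 without WT replicate 1 and 2182 without WT replicate 2, and 2619 and 2430 without MIF_1 replicate 1 or 2. In both sets 745 genes rose and 1101 fell, and 8 genes were called in opposite directions. These were 456 and 620 without WT replicate 1, 530 and 527 without WT replicate 2, 386 and 546 without MIF_1 replicate 1, and 346 and 504 without MIF_1 replicate 2. Simulated unchanged groups set against the same simulated WT libraries shared 0.3 calls in each direction. Independent lists of these sizes would share 93.4 and 150.4. The WT counts were redrawn there, so deviations particular to the real WT libraries, such as those of WT replicate 2, are not in the simulated values. The covariance of the fold changes across genes was 0.52, against 0.05 in the simulations, a difference of 0.47. With 2 WT libraries the controls were not split, so part of the excess may come from the shared controls, and genes are not independent replicates.

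**Figure D2:**
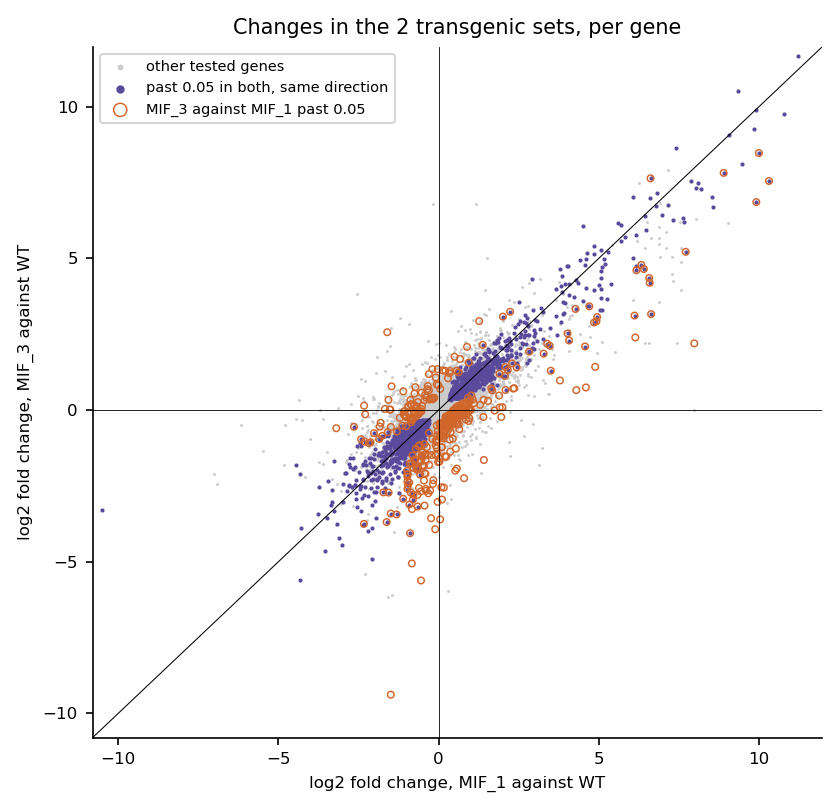
Log2 fold change of each gene tested in MIF_3 against WT (vertical axis) over that in MIF_1 against WT (horizontal axis), with genes called in both sets coloured. Both comparisons share the WT libraries, and 1101 genes fell and 745 rose in both.

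Transcripts of the light-harvesting complexes and photosystems were lower in both sets. LHCA4 (AT3G47470) fell by 0.86 ± 0.10 log2 units (SE; adjusted p = 4.87e-04) in the mean of both sets, from 5230.0 ± 204 CPM (SD, n = 2) in WT to 2394 ± 49.3 in MIF_1 and 3480.0 ± 629.9 in MIF_3. PSBP1 (AT1G06680) fell by 0.83 ± 0.10 (adjusted p = 4.95e-04). Of 40 list members tested, 0 rose, 38 fell and 2 did not pass the test, and 0 rose and 39 fell when adjusted over the list alone. The list lay below other genes, with a median of -0.75 (camera adjusted p = 5.43e-24, but 0.428 with an estimated correlation). The list of electron transport and carbon fixation genes had a median of -0.51 over 18 genes, of which 0 rose, 16 fell and 2 did not pass the test, and 0 rose and 17 fell when adjusted over the list alone. RuBisCO activase, RCA (AT2G39730), fell by 0.49 ± 0.08 (adjusted p = 0.00199), and GAPA (AT3G26650) fell by 0.59 ± 0.08 (adjusted p = 0.00122). That list passed camera (adjusted p = 4.03e-08, but 0.442 with an estimated correlation). RBCS and LHCB genes have near-identical copies among which the counting could split reads.

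Most tetrapyrrole synthesis genes and plastid signalling regulators were also lower. HEMA1 (AT1G58290), whose product makes the first committed precursor of chlorophyll, fell by 1.17 ± 0.19 log2 units (SE; adjusted p = 0.00249), from 920.3 ± 24.6 CPM (SD, n = 2) in WT to 409 ± 19.1 in MIF_1 and 409.9 ± 179.7 in MIF_3. GUN5 (AT5G13630), which codes for a subunit of magnesium chelatase, fell by 0.81 ± 0.09 (adjusted p = 2.50e-04). In the tetrapyrrole list of 26 genes tested, 0 rose, 15 fell and 11 did not pass the test, and 0 rose and 19 fell when adjusted over the list alone. Its median was -0.33 (camera adjusted p = 2.52e-06, but 0.428 with an estimated correlation). Of 2 members left out because the reference did not give their symbols, AT1G74470 was lower by a log2 of -0.59 (adjusted p = 0.00539), and was named after its value was seen. The transcription factors GLK1 (AT2G20570) and GLK2 (AT5G44190) fell by 1.399 ± 0.10 (adjusted p = 2.79e-05) and 0.87 ± 0.10 (adjusted p = 4.38e-04). In the plastid-to-nucleus signalling list of 15 genes, 0 rose, 9 fell and 6 did not pass the test, and 0 rose and 9 fell when adjusted over the list alone. The median of that list was -0.38 (camera adjusted p = 1.08e-05, but 0.428 with an estimated correlation).

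**Figure D3:**
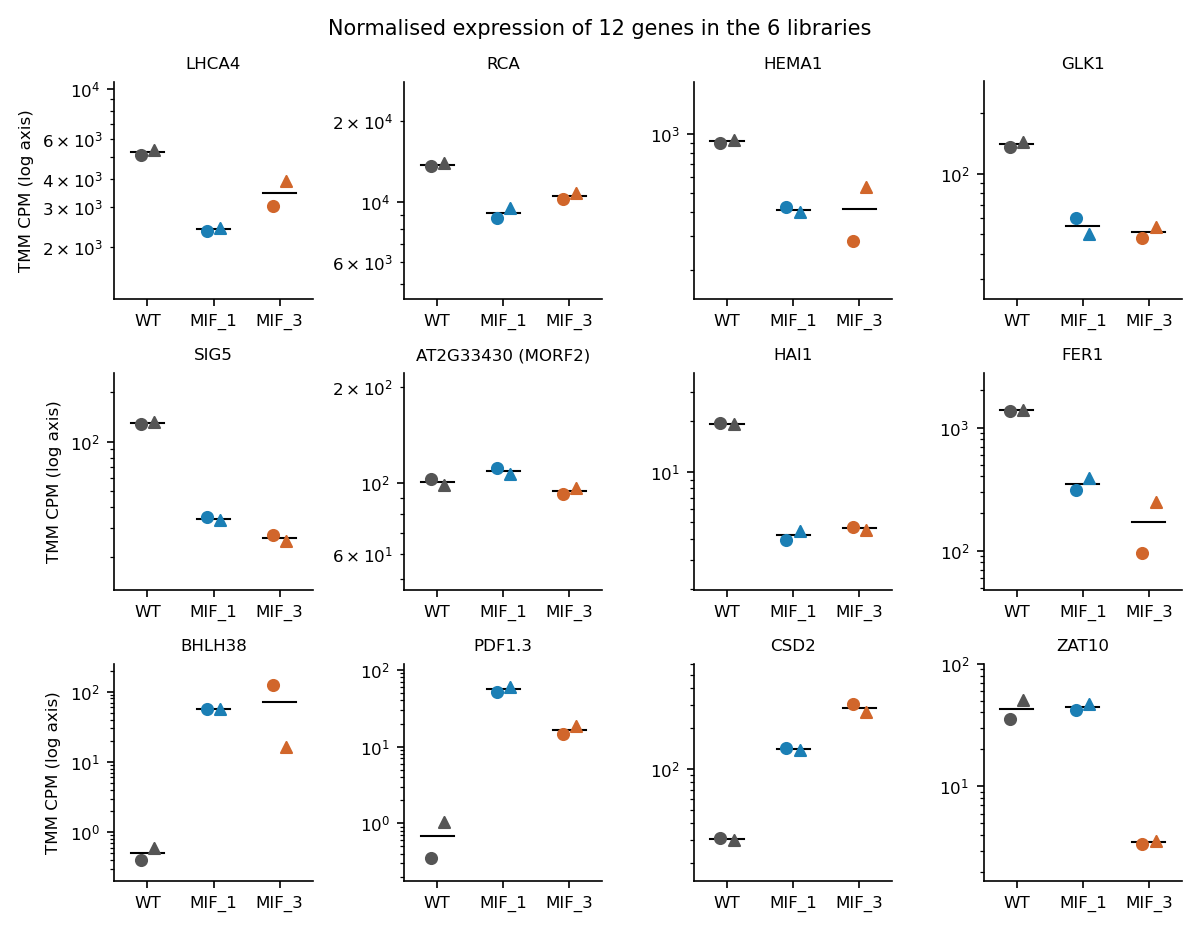
Level (CPM, log axis) of 12 genes in each library, with a circle for replicate 1, a triangle for replicate 2 and a line at the group mean. GLK1, HEMA1 and SIG5 lay lower in each of the 4 transgenic libraries than in both WT libraries, and AT2G33430 did not pass the test.

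Most nuclear genes listed for plastid gene expression did not pass the test. The sigma factor gene SIG5 (AT5G24120) fell by 2.12 ± 0.08 log2 units (SE; adjusted p = 1.33e-06), and SIG1 (AT1G64860) fell by 0.77 ± 0.15 (adjusted p = 0.00665). In the plastid transcription list of 20 genes, 0 rose, 4 fell and 16 did not pass the test, and 0 rose and 5 fell when adjusted over the list alone; the median was -0.14 (camera adjusted p = 0.00448, but 0.428 with an estimated correlation). Among 24 nuclear genes for plastid ribosomal proteins, 0 rose, 7 fell and 17 did not pass the test, and 0 rose and 14 fell when adjusted over the list alone; the median was -0.24 (camera adjusted p = 0.00148, but 0.722 with an estimated correlation). The call of their member with the smallest p, RPS1 (AT5G30510), which fell by 0.42 ± 0.08, ended without WT replicate 1 (adjusted p = 0.0523). The protease gene DEG1 (AT3G27925) fell by 0.49 ± 0.08 (adjusted p = 0.00263). Of 15 plastid chaperone and protease genes, 0 rose, 4 fell and 11 did not pass the test, 0 rose and 7 fell when adjusted over the list alone, and the list did not pass camera (median -0.23, adjusted p = 0.0697). Of 261 pentatricopeptide repeat genes, 1 rose, 6 fell and 254 did not pass the test, and 0 rose and 4 fell when adjusted over the list alone; the median was 0.13 (camera adjusted p = 0.210), and AT2G30100 fell by 1.00 ± 0.10 (adjusted p = 2.34e-04).

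The MORF family and plastid editing factors outside it were tested as lists in each comparison. The MORF list was made by family name, not by whether a member acts in plastids. In the mean of both sets, edgeR called none of 7 MORF genes and none of 16 other editing factors in the lists, over all genes or adjusted over the list alone, where 2 and 4 had an unadjusted p below 0.05. Their medians were 0.13 (camera adjusted p = 0.423) and 0.01 (camera adjusted p = 0.703). In MIF_1 2 MORF genes rose, and 3 when adjusted over the list alone (list median 0.22, camera adjusted p = 0.168). MORF6 (AT2G35240) rose by 0.42 ± 0.12 log2 units (SE; adjusted p = 0.0417), and MORF1 (AT4G20020) rose by 0.38 ± 0.12 (adjusted p = 0.0470). With the replicate block neither MORF6 nor MORF1 passed (edgeR adjusted p = 0.0656 and 0.0729). Their calls ended without WT replicate 1 (0.0667 and 0.101), WT replicate 2 (0.194 and 0.193), MIF_1 replicate 1 (0.149 and 0.205) or MIF_1 replicate 2 (0.156 and 0.116), and in DESeq2 (0.0624 and 0.0760). The editing factor OTP81 (AT2G29760) rose in MIF_1 by 0.81 ± 0.22 (adjusted p = 0.0302), and 0 rose when adjusted over the list alone. Its call ended without WT replicate 1 (0.0832), WT replicate 2 (0.111), MIF_1 replicate 1 (0.0577) or MIF_1 replicate 2 (0.210). In MIF_3 no gene of either list passed, and 0 and 2 had an unadjusted p below 0.05. In MIF_3 against MIF_1 the MORF list lay lower, by a median of -0.21 (camera adjusted p = 0.0390, but 0.931 with an estimated correlation), and 0 genes passed over all genes and 1 fell when adjusted over the list alone. That list call ended without WT replicate 1 (0.0529), WT replicate 2 (0.0519), MIF_1 replicate 1 (0.267) or MIF_3 replicate 1 (0.335). Of 9 editing factors left out of the list because the reference did not give their symbols, AT3G22150, AT1G73530 and AT4G24770 were called in the mean of both sets, with log2 fold changes of -0.48, -0.46 and -0.31 (adjusted p = 0.00668, 0.0121 and 0.0228), and were named after their values were seen. The call of AT3G22150 ended without WT replicate 2 (0.0636), that of AT1G73530 without WT replicate 1 (0.107), and that of AT4G24770 without WT replicate 1 (0.159) or 2 (0.126) or MIF_1 replicate 1 (0.0843) or 2 (0.0614).

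Plastid-encoded transcripts were lower against WT, by an amount that rested on WT replicate 2. ATCG00480 fell by 1.46 ± 0.13 log2 units (SE; adjusted p = 1.18e-04), from 40.1 ± 7.25 CPM (SD, n = 2) in WT to 12.2 ± 2.11 in MIF_1 and 17.2 ± 0.401 in MIF_3. ATCG00490 fell by 2.66 ± 0.45 (adjusted p = 0.00330), and its log2 fold change was -3.41 without WT replicate 1 and -0.99 without WT replicate 2. Of 39 plastid-encoded genes tested among 133 in the table, 0 rose, 18 fell and 21 did not pass the test, and 0 rose and 24 fell when adjusted over the list alone. Their median was -1.52 (camera adjusted p = 4.87e-07, but 0.604 with an estimated correlation) and was -2.43 without WT replicate 1 and -0.25 without WT replicate 2 (camera adjusted p = 0.0375). Among 7 mitochondrion-encoded genes tested of 152, 0 rose, 1 fell and 6 did not pass the test, and 0 rose and 0 fell when adjusted over the list alone. Their median was -1.29 (camera adjusted p = 0.349). The share of mitochondrion-encoded counts was 0.0949% in WT replicate 2 and 0.0276% in WT replicate 1, against 0.0344% to 0.0384% in the transgenic libraries. Only WT replicate 2 thus lay above the transgenic libraries in that share. The gene that fell, ATMG00020, had a log2 fold change of -1.48 ± 0.45 (adjusted p = 0.0475), which was -2.23 without WT replicate 1 and 0.22 without WT replicate 2 (adjusted p = 0.344). Its call also ended without MIF_1 replicate 1 (0.133) or 2 (0.159) without MIF_3 replicate 1 (0.0566) or 2 (0.0569), in DESeq2 (0.200), with the replicate block (0.119) and with the stricter low-count filter (0.0526), and it did not pass in MIF_1 (0.101) or MIF_3 (0.109). In poly(A) libraries such transcripts are mostly left behind, so these levels are a remainder.

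Genes of abscisic acid response were mostly lower. The phosphatase genes HAI1 (AT5G59220) and PP2CA (AT3G11410) fell by 2.14 ± 0.14 log2 units (SE; adjusted p = 1.45e-05) and 1.34 ± 0.12 (adjusted p = 1.03e-04). HAI1 had 19.4 ± 0.279 CPM (SD, n = 2) in WT, 4.197 ± 0.350 in MIF_1 and 4.61 ± 0.131 in MIF_3. CYP707A1 (AT4G19230), which codes for an enzyme that breaks down abscisic acid, rose by 1.51 ± 0.14 (adjusted p = 1.30e-04). Of 29 genes tested, 3 rose, 16 fell and 10 did not pass the test, and 3 rose and 19 fell when adjusted over the list alone; the median was -0.68 (camera adjusted p = 2.42e-08, but 0.428 with an estimated correlation). In the gibberellin list of 23 genes, 2 rose, 8 fell and 13 did not pass the test, 2 rose and 8 fell when adjusted over the list alone, and camera did not pass (median -0.13, adjusted p = 0.0774). The expansin gene EXPA8 (AT2G40610) fell by 2.77 ± 0.20 (adjusted p = 2.68e-05), and RGA (AT2G01570), which codes for a DELLA repressor, fell by 0.66 ± 0.09 (adjusted p = 9.58e-04). Of 28 seed storage and late embryogenesis genes, 10 were counted well enough to be tested. Of these 2 rose, 1 fell and 7 did not pass the test, and 2 rose and 1 fell when adjusted over the list alone; the median was -0.30 where the mean was 1.49 and camera pointed up (adjusted p = 0.377). SESA2 (AT4G27150) rose by 6.55 ± 0.81 (adjusted p = 6.21e-04), and its log2 fold change was 5.91 without MIF_3 replicate 1; SESA genes have close copies among which reads could be split.

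Clock genes moved in both directions. PRR9 (AT2G46790) fell by 2.44 ± 0.20 log2 units (SE; adjusted p = 5.34e-05), from 33.5 ± 6.46 CPM (SD, n = 2) in WT to 5.63 ± 1.91 in MIF_1 and 6.83 ± 1.45 in MIF_3, and CDF1 (AT5G62430) fell by 1.21 ± 0.11 (adjusted p = 1.06e-04). Among 16 clock genes, 2 rose, 6 fell and 8 did not pass the test, and 3 rose and 8 fell when adjusted over the list alone; the median was -0.25 (camera adjusted p = 0.00166, but 0.428 with an estimated correlation). Of 19 light signalling genes, 1 rose, 9 fell and 9 did not pass the test, 2 rose and 9 fell when adjusted over the list alone, and camera did not pass (median -0.31, adjusted p = 0.0670). SPA1 (AT2G46340) fell by 0.64 ± 0.10 (adjusted p = 0.00182) and PIF3 (AT1G09530) fell by 0.81 ± 0.14 (adjusted p = 0.00331). Most cell cycle genes were lower: of 17, 0 rose, 11 fell and 6 did not pass the test, and 0 rose and 12 fell when adjusted over the list alone, with a median of -0.44 (camera adjusted p = 1.20e-04, but 0.428 with an estimated correlation). CYCB1;2 (AT5G06150) fell by 0.81 ± 0.10 (adjusted p = 4.80e-04) and KN (AT1G08560) fell by 0.50 ± 0.09 (adjusted p = 0.00470). Among 16 senescence and sugar starvation genes, 3 rose, 5 fell and 8 did not pass the test, and 4 rose and 6 fell when adjusted over the list alone; the median was -0.24, the mean 0.02, and camera did not pass (adjusted p = 0.234).

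Some defence genes of the jasmonate and ethylene branch were higher. PDF1.3 (AT2G26010) rose by 5.52 ± 0.28 log2 units (SE; adjusted p = 4.08e-06), from 0.688 ± 0.476 CPM (SD, n = 2) in WT to 56.4 ± 6.17 in MIF_1 and 16.7 ± 2.64 in MIF_3. Its log2 fold change was 4.90 without WT replicate 1 and 6.43 without WT replicate 2, and PDF1.2 and PDF1.3 have near-identical copies that could share reads. The chitinase gene CHIB (AT3G12500) rose by 1.16 ± 0.10 (adjusted p = 7.41e-05). Of 18 genes, 7 rose, 2 fell and 9 did not pass the test, and 7 rose and 2 fell when adjusted over the list alone; the median was 0.35 (camera adjusted p = 1.08e-05, but 0.442 with an estimated correlation and 0.133 by fry). Without MIF_3 replicate 2 the median was 0.21 and the call ended (adjusted p = 0.0509). In the salicylic acid list of 25 genes, 7 rose, 4 fell and 14 did not pass the test, 9 rose and 4 fell when adjusted over the list alone, and camera did not pass (median 0.40, adjusted p = 0.275). WRKY70 (AT3G56400) fell by 3.04 ± 0.20 (adjusted p = 1.44e-05). Among 14 glucosinolate synthesis genes, 1 rose, 1 fell and 12 did not pass the test, and 3 rose and 3 fell when adjusted over the list alone; the median was -0.04, the mean was 0.00 and camera pointed up (adjusted p = 0.997). CYP79F2 (AT1G16400) rose by 1.05 ± 0.10 (adjusted p = 1.73e-04), and MYB29 (AT5G07690) fell by 1.16 ± 0.10 (adjusted p = 7.91e-05).

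Genes of reactive oxygen and iron responses moved in both directions. The superoxide dismutase gene CSD2 (AT2G28190) rose by 2.73 ± 0.10 log2 units (SE; adjusted p = 1.08e-06), from 30.2 ± 0.963 CPM (SD, n = 2) in WT to 142 ± 3.47 in MIF_1 and 285 ± 26.3 in MIF_3, and the ferritin gene FER3 (AT3G56090) fell by 1.199 ± 0.15 (adjusted p = 5.61e-04). In the reactive oxygen list of 19 genes, 7 rose, 10 fell and 2 did not pass the test, and 7 rose and 10 fell when adjusted over the list alone; the median was -0.41 where camera pointed up (adjusted p = 0.543). The iron regulator BHLH38 (AT3G56970) rose by 6.99 ± 1.01 (adjusted p = 0.00141), and by 5.93 without MIF_3 replicate 1, which had 3192 counts of it against 409 in MIF_3 replicate 2. BHLH38 and BHLH39 are close copies. Of 11 iron genes, 6 rose, 3 fell and 2 did not pass the test, 7 rose and 3 fell when adjusted over the list alone, and camera did not pass (median 1.15, adjusted p = 0.0670). Members left out of these lists because the reference did not give their symbols are given here where they were called, and were named after their values were seen. For iron both of 2 were higher, AT1G47400 by a log2 of 4.91 (adjusted p = 0.00186) and AT1G47395 by 5.87 (0.00110). AT1G47400 was at 4.23 without WT replicate 1, 5.99 without WT replicate 2 and 4.15 without MIF_3 replicate 1, and AT1G47395 at 5.03 without MIF_3 replicate 1. Among 19 cytosolic heat-shock genes, 6 rose, 2 fell and 11 did not pass the test, and 7 rose and 2 fell when adjusted over the list alone; the median was 0.20 (camera adjusted p = 0.423), and HSFB2A (AT5G62020) fell by 2.33 ± 0.13 (adjusted p = 6.72e-06). Of 4 left out, AT1G53540 was higher by 3.38 (0.00121) and AT5G51440 by 1.000 (0.0106), whose call ended without WT replicate 2 (0.0859). Of 15 mitochondrial dysfunction genes, 5 rose, 2 fell and 8 did not pass the test, and 6 rose and 3 fell when adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.371); SOT12 (AT2G03760) rose by 1.11 ± 0.14 (adjusted p = 6.01e-04). Both of 2 left out were higher, AT2G21640 by 2.23 (1.88e-04) and AT5G09570 by 1.74 (0.00330). In the flavonoid list of 17 genes, 1 rose, 4 fell and 12 did not pass the test, and 1 rose and 4 fell when adjusted over the list alone; the median was 0.09 where the mean was -0.32 and camera pointed down (adjusted p = 0.371). CHS (AT5G13930) rose by 0.48 ± 0.08 (adjusted p = 0.00217), and MYBL2 (AT1G71030) fell by 2.55 ± 0.19 (adjusted p = 3.07e-05).

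Tissue markers, reference genes and the degradation machinery did not pass camera. Of 26 root markers, 3 rose, 2 fell and 21 did not pass the test, and 5 rose and 3 fell when adjusted over the list alone (median 0.12, camera adjusted p = 0.349). The nitrate transporter gene NRT1.5 (AT1G32450) fell by 0.60 ± 0.10 log2 units (SE; adjusted p = 0.00256). Of 14 shoot meristem and stomatal lineage markers, 2 rose, 2 fell and 10 did not pass the test, and 2 rose and 2 fell when adjusted over the list alone (median -0.31, camera adjusted p = 0.580). Of 28 SCF and proteasome core genes, 1 rose, 0 fell and 27 did not pass the test, and 1 rose and 0 fell when adjusted over the list alone (median 0.09, camera adjusted p = 0.254); RPT3 (AT5G58290) rose by 0.37 ± 0.08 (adjusted p = 0.0116), a call that ended without WT replicate 1 (0.0611) or 2 (0.103), and it did not pass in MIF_3 (0.0512). Among 5 common reference genes, 1 rose, 0 fell and 4 did not pass the test, and 1 rose and 0 fell when adjusted over the list alone (median 0.15, camera adjusted p = 0.496). The reference gene called, UBQ10 (AT4G05320), rose by 0.36 ± 0.10 (adjusted p = 0.0365), a call that ended without WT replicate 1 (0.201), WT replicate 2 (0.140) or MIF_1 replicate 2 (0.125), and it did not pass in MIF_1 (0.0711) or MIF_3 (0.0647). Of 204 F-box genes tested among 693 listed, 4 rose, 23 fell and 177 did not pass the test, and 4 rose and 22 fell when adjusted over the list alone; their median was -0.01, their mean 0.03 and camera did not pass (adjusted p = 0.423), and with upper-quartile factors the median was 0.03. MAX2 (AT2G42620), which codes for an F-box protein of strigolactone signalling, fell by 0.76 ± 0.10 (adjusted p = 7.30e-04).

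**Figure D4:**
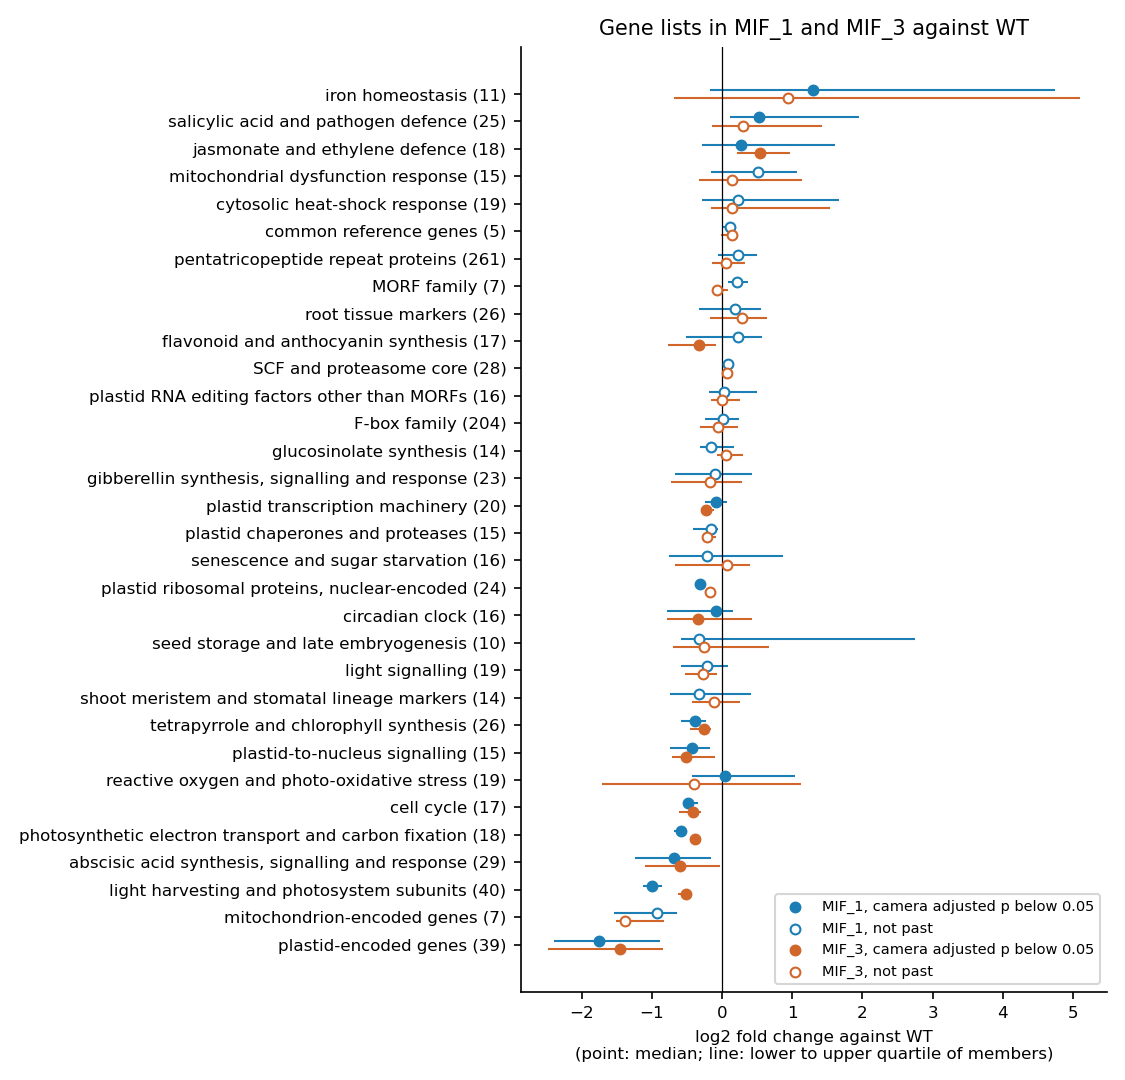
Median log2 fold change against WT of the genes tested in each of 32 lists, with a line from lower to upper quartile, for MIF_1 and MIF_3. Filled points passed camera with its preset correlation, and no list passed with an estimated correlation.

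Among genes called in both sets, the rises with the largest fitted fold changes began from almost no counts in WT. PEN3 (AT5G36150) had 3 counts over both WT libraries, and its pooled ratio over WT was 973 (95% counting interval 333 to 4722) in MIF_1 and 650.3 (222 to 3155) in MIF_3. For LURP1 (AT2G14560), with 1 WT count, that ratio was 1225 (219.6 to 48420) and 426 (76.2 to 16860), and for AT4G36700, also with 1 WT count, it was 1158 (207.5 to 45770) and 1152 (206 to 45520). CYS2 (AT2G31980) rose by 8.35 ± 0.26 log2 units (SE; adjusted p = 2.10e-07) from 17 and 8 counts in WT. No WT count was seen for EXL6 (AT1G75930), AT2G43580, AT1G13609, SESA5 (AT5G54740), AT4G39610 and AT1G07373. Against a floor of 3 counts over the WT group, they were at least 65.4-fold, 85.9-fold, 35.9-fold, 44.0-fold, 119-fold and 161-fold higher in MIF_1 and at least 7.77-fold, 12.6-fold, 36.4-fold, 100.3-fold, 58.8-fold and 221-fold higher in MIF_3, in that order. WT replicate 1 held all WT counts of PEN3, LURP1 and AT4G36700. MIF_3 replicates 1 and 2 differed widely, with 1339 and 242 counts of AT4G36700, 819 and 93 of AT1G07373, 127 and 23 of AT1G13609, 168 and 74 of AT4G39610, and 337 and 76 of SESA5. AT1G13609 and AT1G07373 (without MIF_1 replicate 2, adjusted p = 0.0550 and 0.0557) and SESA5 (without MIF_1 replicate 1, 0.0572) lost their call in MIF_1.

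The largest falls shared by both sets included regulators of senescence and stress. NAP (AT1G69490), a transcription factor of leaf senescence, fell by 4.97 ± 0.28 log2 units (SE; adjusted p = 6.72e-06), from 21.8 ± 0.311 CPM (SD, n = 2) in WT to 1.08 ± 0.700 in MIF_1 and 0.440 ± 0.119 in MIF_3. AIR1 (AT4G12550) fell by 4.11 ± 0.32 (adjusted p = 4.58e-05), PUB19 (AT1G60190) fell by 4.098 ± 0.26 (adjusted p = 1.19e-05) and ORA47 (AT1G74930) fell by 3.50 ± 0.48 (adjusted p = 0.00113). The log2 fold change of ORA47 was -4.15 without WT replicate 1 and -2.29 without WT replicate 2. In MIF_3 alone it was -4.91 (adjusted p = 0.00166) and was called without each library, at -5.56 and -3.70 without WT replicate 1 or 2 and -4.28 and -6.02 without MIF_3 replicate 1 or 2. In MIF_1 it was -2.09 (adjusted p = 0.0261) and -2.74 without WT replicate 1, and the call ended without WT replicate 2 (-0.88, adjusted p = 0.279), MIF_1 replicate 1 (0.187) or 2 (0.130) and in DESeq2 (0.117). AT5G54585, AT4G21930 and AT3G27250 fell by 3.26, 3.19 and 3.15. AT5G33355 fell (adjusted p = 0.00344) from 242 and 65 counts in WT to none in MIF_1 and 1 and 40 in MIF_3. Its call in MIF_3 alone (adjusted p = 0.0470) ended without WT replicate 1 (0.298), MIF_3 replicate 1 (0.0605), MIF_1 replicate 1 (0.0821) or MIF_1 replicate 2 (0.0816), with the replicate block (0.0954), with the compared libraries alone (0.0756) and in DESeq2 (0.414), and that in MIF_1 ended without MIF_1 replicate 1 (0.0639) or 2 (0.0661). The log2 fold change in MIF_3 was -3.29 with all libraries, -2.24 without WT replicate 1 and -2.32 without MIF_3 replicate 1. It was -7.48 without MIF_3 replicate 2 and -3.88 without WT replicate 2, and both kept the call. In MIF_1, at 0 counts, the fitted value depends on the prior count, and leaving out either MIF_1 library hardly moved it (-10.48 and -10.48, against -10.50). ATCG00020 and ATCG00040 fell by 3.59 and 3.45 with all libraries. Their log2 fold changes were -4.47 and -4.30 without WT replicate 1 and -0.91 and -1.19 without WT replicate 2, where the call of ATCG00040 ended (adjusted p = 0.243). Among the genes named, CYS2, AIR1, ORA47, AT4G21930, LHCA4, PSBP1, RCA, GAPA, CHIB, BHLH38, KN, RPT3, CHS, NRT1.5 and CWINV5 overlap another annotated locus, so their counts are uncertain where counting did not use strand.

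MIF_1 against WT asked what differed from WT in that set, whether or not it did in the other. In MIF_1, 1598 genes rose and 2014 fell, 17.7% of those tested. The calls numbered 2122 without WT replicate 1, 2094 without WT replicate 2, 1415 without MIF_1 replicate 1 and 1332 without MIF_1 replicate 2. The rises with the largest fitted fold changes were AT2G43580, AT4G39610 and AT1G07373, at least 85.9-fold, 119-fold and 161-fold higher than the floor of 3 WT counts, and AT1G07373 lost its call without MIF_1 replicate 2 (adjusted p = 0.0557). The largest falls were AT5G33355, with no count in MIF_1, AT3G59930, which fell by 4.44 ± 0.59 log2 units (SE; adjusted p = 0.00125), and NAP, which fell by 4.32 ± 0.34 (adjusted p = 7.67e-05) and by 5.20 without MIF_1 replicate 2. AT5G33355 lost its call without MIF_1 replicate 1 (0.0639) or 2 (0.0661). Of 32 lists, 4 lay above and 10 below other genes by camera, and none did with an estimated correlation (lowest adjusted p = 0.386). The light-harvesting list had a median of -1.002 (camera adjusted p = 3.02e-32), and all 40 genes tested fell. The salicylic acid list had a median of 0.53 (camera adjusted p = 9.91e-04) and the iron list of 1.29 (camera adjusted p = 0.00577); with an estimated correlation both had an adjusted p of 0.386. Without WT replicate 1 the median of the iron list was 1.97. PR1 (AT2G14610) rose by 6.14 ± 0.57 (adjusted p = 1.86e-04) from 0 and 10 counts in WT to 391 and 561 in MIF_1, and by 5.04 without WT replicate 1. Without WT replicate 2, which held all 10 WT counts, WT was at 0 and the fitted log2 fold change, which then depends on the prior count, was 11.87.

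MIF_3 against WT asked the same of the other set. In MIF_3, 1194 genes rose and 1526 fell, 13.3% of those tested. With the WT and MIF_3 libraries alone 1922 genes were called, and 70.0% of the calls were kept. The common dispersion was then 0.0203, against 0.0174 over all 6 libraries. The residual degrees of freedom also fell from 3 to 2. Part of the MIF_3 calls thus rests on including the MIF_1 libraries, which are not in this contrast. Their spread and the added degree of freedom were not told apart. In MIF_1 the calls went the other way, at 4023 with the WT and MIF_1 libraries alone (dispersion 0.0138) against 3612. The shared fit thus narrows the gap in calls between the sets. The calls numbered 1606 without WT replicate 1, 1575 without WT replicate 2 and 1684 without MIF_3 replicate 1. The rises with the largest fitted fold changes were AT1G07373 and SESA5, at least 221-fold and 100.3-fold higher than the floor of 3 WT counts, and AT4G36700, whose pooled ratio over WT was 1152 (95% counting interval 206 to 45520). MIF_3 replicates 1 and 2 had 819 and 93 counts of AT1G07373, 337 and 76 of SESA5, and 1339 and 242 of AT4G36700. CBF2 (AT4G25470), a cold-response regulator, fell by 5.62 ± 0.47 log2 units (SE; adjusted p = 9.79e-05), from 14.1 ± 7.40 CPM (SD, n = 2) in WT to 0.278 ± 0.109, and by 4.96 without WT replicate 2. RTFL12 (AT4G13395) fell by 5.06 ± 0.44 (adjusted p = 1.17e-04) and NAP fell by 5.62 ± 0.39 (adjusted p = 3.02e-05). By camera 1 list, jasmonate and ethylene defence, lay above other genes and 10 below, and none did with an estimated correlation (lowest adjusted p = 0.518). The jasmonate and ethylene list had a median of 0.54 (camera adjusted p = 6.32e-05), which was 0.16 without MIF_3 replicate 2 (0.474). The light-harvesting list had a median of -0.51 (camera adjusted p = 3.43e-11), and 0 rose, 24 fell and 16 did not pass the test. Its median depended on the MIF_3 library, at -0.316 without MIF_3 replicate 1 and -0.783 without MIF_3 replicate 2. Flavonoid genes had a median of -0.33 (camera adjusted p = 0.00230, but 0.518 with an estimated correlation), and the plastid-encoded list, with a median of -1.46 (camera adjusted p = 2.50e-05), had one of -2.32 without WT replicate 1 and lost its call without WT replicate 2 (median -0.19, adjusted p = 0.0861).

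MIF_3 against MIF_1 tested the difference between the sets itself. In MIF_3, 97 genes were higher and 263 lower than in MIF_1, 1.8% of those tested. The zinc-finger gene ZAT10 (AT1G27730) was lower by a log2 of -3.65 ± 0.19 (SE; adjusted p = 5.22e-05), with 42.9 ± 10.2 CPM (SD, n = 2) in WT, 44.2 ± 3.28 in MIF_1 and 3.51 ± 0.163 in MIF_3. CBF2 differed by -5.07 ± 0.48 (adjusted p = 0.00138) and AT1G67865 by 2.59 ± 0.21 (adjusted p = 4.76e-04). The calls numbered 20 without MIF_1 replicate 1 and 53 without MIF_1 replicate 2. Of 26 named genes called here, 23 lost their call without at least 1 library, and the 3 that kept it were ZAT10, CBF2 and AT1G67865. The other largest differences were -4.22 in RTFL12, -3.75 in PR1, -3.47 in ENODL1 (AT5G53870) and -3.06 in EXL6 below MIF_1, and 4.17 in FAMT (AT3G44860), 2.47 in AT4G33720, 2.25 in CWINV5 (AT3G13784) and 2.15 in MLP168 (AT1G35310) above it. All 8 calls ended without MIF_1 replicate 1, at an adjusted p of 0.0591, 0.0864, 0.0916, 0.124, 0.396, 0.221, 0.252 and 0.137 in that order. Without MIF_1 replicate 2 those of PR1 (0.101), EXL6 (0.140), FAMT (0.254), AT4G33720 (0.222), CWINV5 (0.128) and MLP168 (0.185) ended as well. FAMT also lost its call without WT replicate 1 (0.0523), WT replicate 2 (0.0519) or MIF_3 replicate 2 (0.130, log2 of 2.06), and CWINV5 lost it without MIF_3 replicate 2 (0.0803). The difference in FAMT was 4.99 without MIF_3 replicate 1. The light-harvesting list was higher in MIF_3 than in MIF_1, by a median of 0.45 (camera adjusted p = 3.20e-16, but 0.753 with an estimated correlation); 1 of its 40 genes, PSAL (AT4G12800), rose, and 30 did when adjusted over the list alone. The call of PSAL ended without MIF_1 replicate 1 (0.385), MIF_1 replicate 2 (0.243), WT replicate 1 (0.0708) or WT replicate 2 (0.0700). By camera 5 lists lay above and 6 below other genes, and none did with an estimated correlation (lowest adjusted p = 0.437). By fry, which tests a list against no change, 0 lists passed.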

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

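The tests on light-harvesting, plastid-encoded and defence transcripts in this part were chosen only after the results were seen; the contrast of MIF_3 with MIF_1 was planned. The genes and lists of the next 2 paragraphs were set apart by that contrast, a test of the difference between MIF_3 and MIF_1 itself. The 3 patterns after them were weighed for their difference from WT, and the plastid-encoded list did not pass between the sets (camera adjusted p = 0.805).

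Genes lower in MIF_3 than in MIF_1, on the log2 scale, were CBF2 at -5.07, RTFL12 at -4.22, PR1 at -3.75, ZAT10 at -3.65, ENODL1 at -3.47, EXL6 at -3.06, AT2G43580 at -2.76 and DIC2 at -2.71. Smaller differences were PDF1.3 at -1.76, WRKY40 at -1.63, LURP1 at -1.53, WRKY70 at -1.42, WRKY53 at -1.38, WRKY33 at -1.14, CYS2 at -1.08, CHIB at -1.03 and UGT78D2 at -0.88. Genes higher in MIF_3 were FAMT at 4.17, AT1G67865 at 2.59, AT4G33720 at 2.47, CWINV5 at 2.25, MLP168 at 2.15, FAMA at 1.03, CSD2 at 1.00, MYB29 at 0.86 and PSAL at 0.62. Of these 26 genes, 23 lost their call without at least 1 library. FAMT rested on MIF_3 replicate 2, with 449 counts against 60 in MIF_3 replicate 1, and its adjusted p without that library was 0.130. PR1 had an adjusted p of 0.135 in DESeq2.

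Lists higher in MIF_3 than in MIF_1 had median log2 differences of 0.45 for light harvesting, 0.20 for electron transport and carbon fixation, 0.17 for abscisic acid, 0.15 for plastid ribosomal proteins and 0.15 for glucosinolates. Lists lower in MIF_3 had medians of -0.73 for flavonoids, -0.43 for salicylic acid, -0.29 for mitochondrial dysfunction, -0.21 for MORF genes, -0.17 for reactive oxygen and -0.11 for pentatricopeptide repeat genes. None of the 11 passed with an estimated correlation, where the lowest adjusted p was 0.437. The calls of light harvesting, flavonoids, salicylic acid and mitochondrial dysfunction were kept without each library, and each of the other 7 ended without at least 1. Without MIF_1 replicate 1 the adjusted p was 0.267 for MORF genes, 0.568 for abscisic acid, 0.119 for glucosinolates, 0.119 for plastid ribosomal proteins and 0.337 for pentatricopeptide repeat genes. Without MIF_3 replicate 1 it was 0.335 for MORF genes, 0.494 for abscisic acid (median -0.024, of opposite sign), 0.190 for reactive oxygen (median 0.024, of opposite sign) and 0.0709 for pentatricopeptide repeat genes. Without MIF_3 replicate 2 it was 0.457 for electron transport and carbon fixation (median 0.09), 0.127 for plastid ribosomal proteins, 0.306 for glucosinolates and 0.127 for pentatricopeptide repeat genes. Without WT replicate 1 or 2 it was 0.0529 and 0.0519 for MORF genes and for glucosinolates, and 0.0518 and 0.0511 for pentatricopeptide repeat genes.

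Light-harvesting and photosystem transcripts were lower in both sets than in WT. The library of WT replicate 2 alone does not account for this, since without it the median was -0.731, against -0.748 with all libraries. A smaller share of green tissue would lower both photosynthesis lists alike if both came from it to the same degree. That was not measured. In the mean of both sets the light-harvesting median differed from the electron transport and carbon fixation median by -0.238 (permutation test over genes, p = 6e-05). This came mostly from MIF_1, where the difference was -0.412 (permutation test over genes, p = 2e-05), and from -0.45 to -0.377 when 1 library was left out. In MIF_3 it was -0.124 (permutation test over genes, p = 0.00418), -0.053 without MIF_3 replicate 1 and -0.271 without MIF_3 replicate 2. An equal fall was thus not seen in MIF_1, but genes are not independent replicates. A smaller share of green tissue therefore stays open in both sets. A different clock phase at harvest may contribute: 7 clock genes that peak in the morning had a mean of -0.996 and 6 that peak in the evening a mean of 0.65, a difference of -1.65 (exact permutation test over genes, two-sided, p = 0.00117), which was -1.47 in MIF_1 (p = 0.00233) and -1.83 in MIF_3 (p = 0.00117). The members did not move alike. PRR9 at -2.44 lay lowest of the morning genes, of which 5 fell and kept their call without each library, while RVE8 (-0.39, adjusted p = 0.0589) and LHY (-0.14, 0.558) did not pass. The evening mean rested on ELF4 at 1.78 (0.0191) and on PRR5 at 1.32, which did not pass (0.0826); GI (-0.11, 0.602), LUX (0.22, 0.246) and ELF3 (0.30, 0.245) did not pass either. The 2 evening genes called lost their call, ELF4 without WT replicate 2 (0.119) or MIF_1 replicate 2 (0.0699), and TOC1 at 0.41 (0.0295) without WT replicate 1 (0.159) or 2 (0.0932), MIF_1 replicate 1 (0.0838) or 2 (0.0529) or MIF_3 replicate 1 (0.0755). The evening side of a shift therefore rests on few genes. The effect of MIF itself stays open, could also act through the clock, and cannot be told apart from that of the vector.

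Plastid-encoded transcripts were lower in both sets than in WT. RNA without poly(A) tails carried into WT replicate 2 may account for most of this, since the median was -1.519 with all libraries and -0.252 without that library. The nuclear rRNA share of that library, 1.04%, also lay above the 0.437% of WT replicate 1. Without it the list still passed camera in the mean of both sets (adjusted p = 0.0375) but not in MIF_3 alone (median -0.19, adjusted p = 0.0861), and with an estimated correlation and all libraries it did not pass in the mean either (0.604). Some genes of the list were still called lower without it in that mean, among them ATCG00480 at -1.27 (0.00138), ATCG00490 at -0.99 (0.00509) and ATCG00020 at -0.91 (0.00402), so a smaller fall remained in these genes, with 1 WT library to set it against. Whether it holds for the list as a whole is open, as is an effect of MIF or of the vector on it. The failure with an estimated correlation does not bear on this, since 0 lists passed that test in any contrast.

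Some defence transcripts, such as PDF1.2 and PR1, were higher in both sets or in MIF_1. In the mean contrast 7 jasmonate and ethylene genes rose, 2 fell and 9 did not pass the test. Of the salicylic acid genes 7 rose, 4 fell and 14 did not pass in that contrast, and in MIF_3 4 rose and 5 fell. The rise of PDF1.2 was 5.85 without WT replicate 1 and 8.31 without WT replicate 2. A candidate explanation is the inducible vector system, whose dexamethasone-activated transcription factor was present in both sets and not in WT. The 0 libraries of seedlings with the vector and without MIF leave it open. The vector and MIF cannot be told apart for these genes, nor for any other difference from WT.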

How the results depend on the processing

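All alternatives but the joint removal of organelle-encoded and rRNA genes were planned. Under the alternatives no called gene, of all genes tested, was called in the other direction. Over all settings, counts of calls stayed within 1.5 times in 211 cases, grew in 14 and shrank in 69. The adjusted p of lists kept its side of the threshold in 1812 cases, passed it anew in 70 and lost it in 114. For named genes these were 9349, 119 and 658, with 1 turned. Lists and genes that were not called under either setting are among those that kept their side. These tallies therefore do not measure how stable the calls were.

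At a threshold of 0.01, calls higher and lower were 665 and 910 in MIF_1, 446 and 697 in MIF_3, 669 and 1196 in the mean contrast and 16 and 85 in MIF_3 against MIF_1, with 311 and 443 in both sets. With a log2 limit of 1 they were 648 and 515, 550 and 499, 591 and 550, and 43 and 134, with 358 and 250 in both sets. Stricter limits call fewer genes by construction. With the libraries compared alone, 784 genes were higher in MIF_3 than in WT. In MIF_3 against MIF_1, 242 genes were higher and 445 lower with no low-count filter, and 262 and 477 in DESeq2; the cause was not tested.

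With an estimated correlation, 0 lists were higher and 0 lower in each of the 4 contrasts. By fry, which tests a list against no change, 13 lists passed in MIF_1. There were 0 higher and 5 lower in MIF_3, 0 higher among 10 that passed in the mean contrast, and 0 in MIF_3 against MIF_1. Jasmonate and ethylene (0.133), light harvesting (0.0513), abscisic acid (0.0501), plastid ribosomal proteins (0.0782) and plastid-encoded genes (0.240) passed camera but not fry in the mean contrast. Plastid chaperones and proteases (0.0300), gibberellin (0.0300), light signalling (0.0415) and F-box genes (0.0327) passed fry but not camera. With no low-count filter 2 lists were higher in the mean contrast. The cause was not tested.

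Leaving out each library in turn gave from 546 to 1797 genes higher and 776 to 2169 lower in MIF_1, 669 to 1105 and 838 to 1330 in MIF_3, 842 to 1647 and 1215 to 2196 in the mean contrast, and 2 to 239 and 18 to 306 in MIF_3 against MIF_1. In both sets 346 to 749 rose and 504 to 1064 fell. Lists higher numbered 1 to 3 in MIF_3, 1 to 3 in the mean contrast and 2 to 6 in MIF_3 against MIF_1. Fewer libraries leave 2 residual degrees of freedom. ATMG00020 in the mean contrast went from -1.48 to 0.22 without WT replicate 2 and to -2.23 without WT replicate 1; WT replicate 2 is the library with the largest organelle-encoded share.

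The replicate numbers did not pair the samples: differences between replicates 1 and 2 correlated at -0.04, -0.04 and 0.04 across genes between groups. With the replicate block 1382 genes were higher and 1745 lower in MIF_1, 997 and 1366 in MIF_3, 1419 and 2042 in the mean contrast, and 75 and 220 in MIF_3 against MIF_1. Of the calls 84.3%, 84.3%, 87.8% and 71.9% were kept. The block ended the list calls of plastid transcription and reactive oxygen in MIF_1 (adjusted p = 0.0593 for both).

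Depth limits genes with few counts: 20438 of 32834 loci were tested, and 10 of 28 seed storage genes. Changes of 1.5-fold were recovered in 20.1% to 35.8% of simulated cases in the 3 contrasts against WT. Far fewer genes were changed there than the 13.3% to 18.7% called in the data, which makes the adjusted threshold stricter. This recovery therefore does not carry over to the data. Some changes smaller than 1.5-fold were called, such as log2 fold changes of -0.36 in GUN1 and -0.31 in CLPC1 in the mean contrast.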

Other observations

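The test on F-box loci was chosen only after the results were seen; the iron test was written before its result was known. Both are hypotheses formed on these data.

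The iron regulator genes BHLH38 and BHLH39 were higher and the ferritin genes FER1 and FER3 lower in the mean of both sets than in WT, which may be part of a wider iron-deficiency response. A second list of 15 iron uptake genes and targets of the regulator PYE was higher in the mean of both sets, with a median log2 fold change of 1.08 (camera p = 5.15e-07, but 0.128 with an estimated correlation). Of these genes 8 rose and 0 fell. Tissue iron was not measured, and the MIF_3 replicates differed for BHLH38, with 3192 and 409 counts.

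The induced MIF transcript might be counted at a locus annotated as F-box, since the series title names F-box control. Of 693 such loci 333 had counts and 204 were tested. The largest fold over WT reached in both sets was 7.53, at AT5G55150, with no count in WT, 20 and 12 in MIF_1 and 2 and 29 in MIF_3. Against a floor of 3 WT counts it was at least 8.14-fold higher in MIF_1 and at least 7.53-fold higher in MIF_3. It did not pass edgeR (adjusted p = 0.0687 and 0.0881) but passed DESeq2 (0.0135 and 0.0183). The largest called rise in the mean contrast was at AT2G17036, by 1.43 on the log2 scale (adjusted p = 0.0192). Both loci were chosen after their values were seen. These counts are too few to decide, and a transgene whose reads were not counted at an annotated locus would show no rise at all.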
